A study of Homo sapiens with 5 samples.

How the data were processed

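Droplet-based single-cell RNA libraries of 5 groups, 1 library each, were analysed: ePP, EP, R6d8 WT, R6d8 C16-KO and R7d5. The values are UMI counts per gene and barcode for 36601 genes, which the authors made with Cell Ranger against genome build hg38 and deposited as matrices of the barcodes called as cells. The authors' notes list Cell Ranger 7.1.0 for every library, while the file headers gave 7.0.0 for both R6d8 libraries. How cells were prepared beyond the media named in the labels is not given in the sources used here. Gene positions were taken from GENCODE release 29, which placed 34616 of the genes.

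Barcodes were kept with at least 1000 genes and at most 20% mitochondrial UMIs. Above the mitochondrial limit lay 287 barcodes of ePP, 78 of EP, 842 of R6d8 WT, 113 of R6d8 C16-KO and 1309 of R7d5. Doublets were called per library with Scrublet as in scanpy 1.11.5, at an expected rate of 0.06, and removed. Its automatic threshold called 0.0% of ePP and 0.0938% of R7d5, under a minimum of 0.5%, so the median threshold of the other 3 libraries, 0.211, was used for both; this rule was chosen after seeing the data. Doublets were then 6.48% of ePP, 4.42% of EP, 7.62% of R6d8 WT, 4.74% of R6d8 C16-KO and 4.14% of R7d5 barcodes that passed the filters.

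Kept cells of all libraries were clustered together on 2000 variable genes with 30 principal components, 15 neighbours and Leiden resolution 1 with 4 iterations (leidenalg 0.10.2), which gave 29 clusters. No correction between libraries was applied. A cluster took the name of the class with the most markers at 20 CPM or more and at least 2-fold over the other clusters, with at least 3 markers and the first-listed one among them. It stayed unnamed on a tie, when its 10 leading genes held more markers of another class, or under a rule on low UMIs per cell. These naming thresholds were set after seeing the data, and classes with at least 200 cells in both R6d8 libraries were compared. Shares have exact Clopper-Pearson intervals. The share of cells with a UMI of a gene was also counted after thinning each cell to 5000 UMIs.

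For comparisons the UMIs of kept cells were summed per library or per class and divided by their total to give CPM; log2 ratios used a pseudocount of 1 CPM. Ratios have exact conditional binomial intervals at 95%. The ratio of median INS levels in GCG-high cells has a bootstrap interval from 2000 resamples of cells. A count of 0 was set to a floor of 3 counts over the library or class for a bound on the fold. The genes named were the 12 with the highest and the 12 with the lowest log2 ratio among those at 20 CPM or more in either library (8 and 8 within classes), and 9 genes named in every comparison. Mitochondrial and ribosomal protein genes, genes named after a clone or contig, XIST and genes of chromosome Y were left out of that rule. Where stated, list medians were adjusted by taking the median of each of 20 bins of gene span off the log2 ratios and adding back the median of all genes. List members named were those with the largest ratios in the list's direction or against it. Gene lists, 28 in number, were described by the median log2 ratio of members at 10 CPM or more, set against 10000 random lists matched in 20 bins of mean expression. Because each group had 1 library, no test between groups was made.

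For the 24 genes named per comparison, the upper limit of the ratio was at the median 1.33 (EP over ePP), 1.18 (R6d8 WT over EP), 1.14 (R7d5 over R6d8 WT) and 1.10 (C16-KO over WT) times the lower limit; the widest was LRRC61 in C16-KO over WT, at 29.8 times on 2 UMIs. The intervals of ratios were tested on simulated Poisson counts, the spread they assume. Between 95.1% and 95.3% held the true ratio, and 24 of 24 named genes were among those changed. The naming was tested on 1200 simulated cells, of which 100.0% were given their class. Those cells were drawn from the summed R6d8 WT profiles of 4 classes that the rule had already named. They held no unnamed kinds and no variation beyond counting, so the result does not show how well real cells were named. Alternatives to scaling (TMM factors from edgeR 4.0.16, median-of-ratios size factors, totals without 7 hormone genes), pseudocount (0.1 and 10), cell weights, cell filters, doublets, Leiden resolution (0.5 and 2), clustering genes and the CPM minimum were run. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and R 4.3.3.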

Results

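Single-cell gene expression was measured with a droplet method in 5 libraries made from MEL1, a human embryonic stem cell line, and each library was a group of its own. The groups were expandable pancreatic progenitors (ePP), which were grown on feeder cells, endocrine precursors made from them (EP), and islet-stage cells in R6 medium at day 8 (R6d8), wild type (WT) or with a knockout that the labels call C16-KO. The last group was wild-type islet-stage cells in R7 medium at day 5 (R7d5). The files held 146307871 unique molecular identifiers (UMIs) in 7450 barcodes for ePP, 120379605 in 10630 for EP, 253268238 in 9587 for R6d8 WT, 249022121 in 8973 for R6d8 C16-KO and 168012149 in 8096 for R7d5. After filters on cell quality and doublets, 6681, 9595, 7658, 7960 and 6134 cells were kept, in the same order, with median depths of 17681, 10826, 24192, 26659 and 21074 UMIs per cell. There were no replicate libraries, so every value describes a single library, no test was made across libraries, and the intervals (95%) cover counting error, or in the case of INS in GCG-high cells the sampling of cells, and no difference between libraries made alike. Levels are CPM, the UMIs summed over kept cells and scaled to the library total, and list medians are of log2 ratios of CPM + 1. The headers of the count files gave Cell Ranger version 7.1.0 for ePP, EP and R7d5 and 7.0.0 for both R6d8 libraries. R6d8 WT against EP and R7d5 against R6d8 WT therefore crossed versions, and in those comparisons the processing batch and the group cannot be told apart.

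The libraries differed in which kinds of cells they held. Clusters were named after fixed marker genes, with thresholds that were set after seeing the data, and a name ends in "-like" because it rests on markers alone. Alpha-like cells, named by the glucagon gene GCG and other alpha-cell markers, made up 18.0% of R6d8 WT cells (95% Clopper-Pearson interval 17.2 to 18.9), 15.1% of R6d8 C16-KO cells (14.3 to 15.9) and 42.8% of R7d5 cells (41.6 to 44.1). Enterochromaffin-like cells, named by TPH1 (the rate-limiting enzyme of serotonin synthesis in the gut) and related markers, made up 27.2% (26.2 to 28.2), 26.1% (25.1 to 27.1) and 39.8% (38.6 to 41.0) of those libraries. Beta-like cells, named by INS (insulin) and related markers, made up 7.22% (6.65 to 7.82), 5.90% (5.40 to 6.45) and 12.7% (11.8 to 13.5). None of these classes held a cell among the 6681 of ePP, which allows a share of up to 0.0449% each at a limit of 3 cells, and in EP they held 0.938%, 0.0834% and 0.146% of cells. Across the alternatives of processing, the alpha-like share ran from 12.4% to 20.5% in R6d8 WT and from 8.72% to 16.6% in C16-KO, the enterochromaffin-like share from 17.3% to 31.0% and from 15.1% to 30.1%, and the beta-like share from 4.11% to 8.45% and from 3.96% to 5.96%. A name holds for a cluster and not for each of its cells. Of alpha-like cells, 26.0% in R6d8 WT and 8.56% in C16-KO reached 1000 CPM of GCG. Summed over the class, INS (24456 and 9357 CPM) exceeded GCG (6585 and 1902 CPM) in these libraries.

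Endocrine precursor-like cells, named by NEUROG3 (the transcription factor that starts the endocrine program), made up 21.7% of EP cells (20.9 to 22.5). They were 0.967% of R6d8 C16-KO (0.764 to 1.21), 0.144% of R6d8 WT (0.0717 to 0.257) and 0.0978% of R7d5, and none was seen in ePP. Proliferating-like cells made up 53.8% of ePP (52.6 to 55.0), 0.365% of EP, 7.16% of R6d8 WT, 8.28% of R6d8 C16-KO and 0.293% of R7d5. The ePP and EP shares also depended on the processing: proliferating-like cells were between 17.6% and 58.7% of ePP and endocrine precursor-like cells were between 11.6% and 38.0% of EP across the alternatives. A cluster called duct-like held 0.778% of ePP and no cells of the other 4 libraries. It was named by KRT19, TFF1, TFF2 and CLDN18, of which the last 3 are also genes of stomach epithelium, so its name is uncertain. The alpha-like cells of both R6d8 libraries lay mostly in cluster 2 and those of R7d5 in cluster 3. The enterochromaffin-like cells of R6d8 WT, R6d8 C16-KO and R7d5 lay mostly in clusters 9, 7 and 4, and the beta-like cells in clusters 15, 15 and 18. The ePP proliferating-like cells lay mostly in cluster 5, those of both R6d8 libraries in cluster 14, and the EP precursor-like cells in cluster 6.

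Clusters without a name held 45.4% of ePP, 76.8% of EP, 40.2% of R6d8 WT, 43.6% of R6d8 C16-KO and 4.32% of R7d5. The naming thresholds kept out clusters whose best match was pancreatic progenitor in 44.5% of ePP cells, 10.2% of R6d8 WT cells and 12.1% of R6d8 C16-KO cells. They also kept out clusters that best matched liver in 36.4% of EP cells and endocrine precursor in 16.1% of EP cells. A cluster with a tie between progenitor and liver markers held 14.5% of R6d8 WT and 11.6% of R6d8 C16-KO cells, and an epsilon match (ghrelin gene GHRL) held 5.48% and 2.90%. Cluster 19, with too few markers of any class, held 2.08% of R6d8 WT and 7.11% of R6d8 C16-KO cells.

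**Figure D1:**
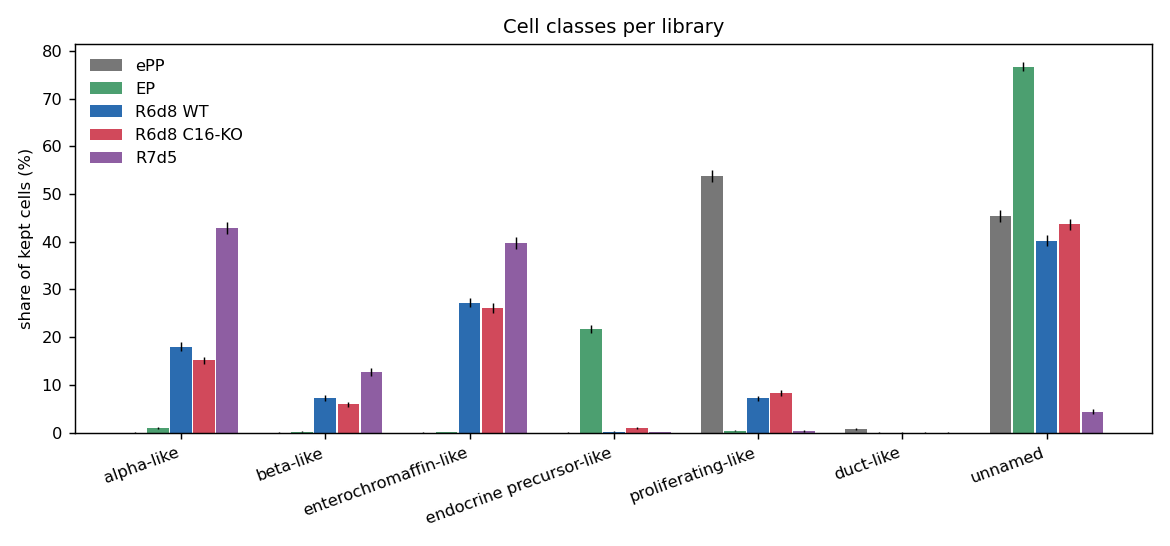
Share of kept cells (percent) given to each marker-based class in each of the 5 libraries, with 95% Clopper-Pearson intervals that cover counting error only. Alpha-like cells were 42.8% of R7d5 and 18.0% of R6d8 WT.

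The levels of 9 marker genes that were fixed in advance differed between the libraries as follows. INS was at 0 UMIs in ePP (floor 0.0231 CPM), 973 CPM in EP, 10242 CPM in R6d8 WT, 4982 CPM in R6d8 C16-KO and 37729 CPM in R7d5. GCG was at 0, 48.4, 1166, 290.5 and 7603 CPM in the same order, and SST, the somatostatin gene, at 0.00769 (1 UMI), 10.4, 37.1, 56.0 and 744 CPM. TPH1 was at 1.68, 72.6, 505, 407 and 672 CPM. NEUROG3 was at 0.0846, 46.1, 1.60, 4.78 and 0.474 CPM. PDX1 and NKX6-1, transcription factors of pancreatic progenitors and beta cells, were at 84.5 and 132 CPM in ePP and at 32.7 and 69.8 CPM in R7d5. SOX9, a factor of progenitors and duct cells, was at 141 CPM in ePP, 41.0 in EP, 25.2 in R6d8 WT, 30.8 in R6d8 C16-KO and 5.34 in R7d5. The proliferation marker MKI67 was at 83.4, 10.3, 18.4, 17.5 and 3.29 CPM in those libraries.

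With every cell thinned to 5000 UMIs, 13.6% of EP cells (12.9 to 14.4) had a NEUROG3 UMI, against 0.0607% of ePP cells (0.0165 to 0.155). The unthinned shares were 20.3% and 0.0748%, and 772 EP and 86 ePP cells shallower than 5000 UMIs were left out. MKI67 was seen in 25.7% of thinned ePP cells, 3.20% of EP cells, 5.04% of R6d8 WT cells, 4.85% of R6d8 C16-KO cells and 0.745% of R7d5 cells. The unthinned MKI67 shares were 47.8%, 5.62%, 13.0%, 13.4% and 1.81%, and 500 R6d8 WT, 437 C16-KO and 228 R7d5 cells were left out. As a background, alpha-like cells, which are not named by division genes, held a MKI67 UMI in 0.676% of R6d8 WT, 0.672% of R6d8 C16-KO and 0.155% of R7d5 thinned cells, at median depths of 21422, 24492 and 22284 UMIs.

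**Figure D2:**
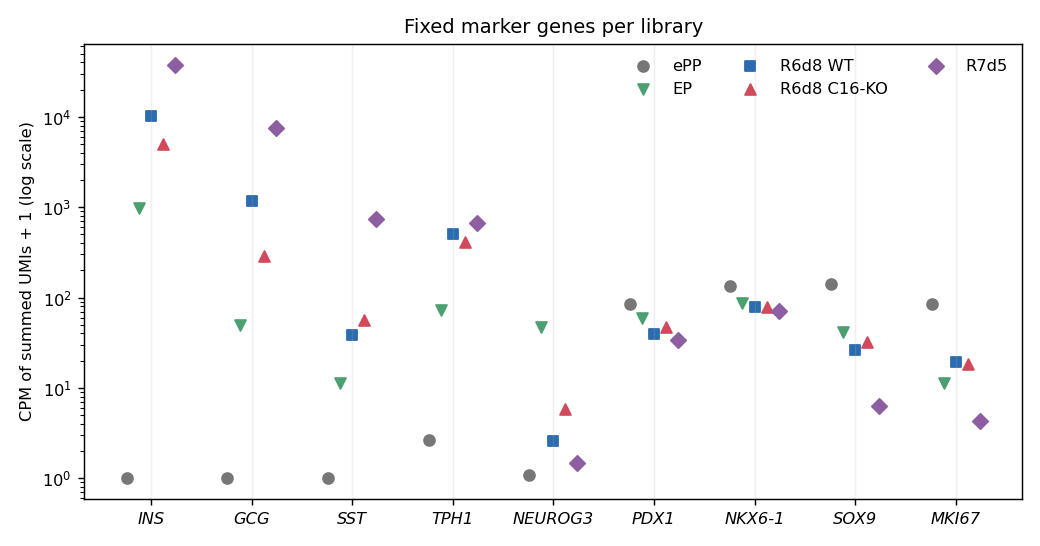
CPM + 1 (log scale) of 9 marker genes fixed in advance, each point a library. INS ran from 0 CPM in ePP to 37729 CPM in R7d5.

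EP against ePP asked how the endocrine precursors differed from the progenitors they were made from. Hormone and secretory genes stood far higher in the EP library. Feedback inhibitors of the ERK pathway and the BMP targets ID3 and ID1 were among the genes that were far lower. CHGA, which encodes the granule protein chromogranin A, was 2205-fold higher in EP (3476 CPM against 1.58; interval 1923 to 2541), and INS was at least 42165-fold higher against a floor of 3 counts over the ePP library. TTR (transthyretin, made by islet and liver cells) was 947-fold higher, CRYBA2 3693-fold and PRSS2, a trypsinogen gene, 700.4-fold. The fibrinogen genes FGB and FGG were 16443-fold and 10402-fold higher, on 9 and 4 UMIs in ePP. Also among the genes with the highest ratios were the potassium channel KCNB2 (1927-fold), the presynaptic protein RIMS2 (972-fold) and the calcium channel CACNA1A (396-fold). The sialyltransferase ST6GALNAC5 (639-fold) and the calcium release channel RYR2 (311-fold) were among them too. Whether ion channel genes as a group were higher was not tested. PRSS2 has near-identical relatives, so its level is uncertain.

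Lower in EP were the long noncoding RNA LHFPL3-AS2 (81.9-fold) with its neighbour LHFPL3 (20.8-fold), and SHISA2 (62.6-fold), an antagonist of FGF and WNT receptors. SULF1, a sulfatase that edits heparan sulfate, was 37.8-fold lower. SPRY4, SPRY2 and DUSP6, feedback inhibitors of the ERK pathway, were 34.1-fold, 14.0-fold and 13.2-fold lower, and ID3 and ID1, targets of BMP signalling, 24.7-fold and 15.03-fold. The neural transcription factor POU3F2 (14.7-fold), C8orf34 (13.2-fold) and MEGF10 (13.5-fold) completed the 12 lowest. SOX9 was 3.43-fold lower and MKI67 8.13-fold lower, while PDX1 and NKX6-1 were 1.46-fold and 1.52-fold lower.

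Of 22 measured cell cycle genes, 20 were at least 2-fold lower in EP and 0 were higher (median log2 ratio -2.28, percentile 0.0 among random lists of like expression), among them MKI67 (-2.91), BIRC5 (-2.79) and TOP2A (-2.71). Of 14 ERK targets, 11 were lower and 1, DUSP4 (1.01), was higher (median -2.21). The Notch list had a median of -1.28, with 5 of 10 members lower, among them HEY1 (-3.29) and JAG1 (-3.30), and 2 higher, the ligand genes DLL1 (1.78) and DLL4 (2.85). BMP targets had a median of -0.98 with 4 of 8 lower, and pancreatic progenitor genes of -0.53 with 3 of 9 lower. In the other direction, 13 of 19 islet transcription factors were at least 2-fold higher in EP (median 3.93), including NEUROD1 (7.03) and INSM1 (7.01). Hormone genes (median 5.63, 7 of 7), secretory genes (3.76, 19 of 21) and glucose-sensing genes (4.09, 14 of 15) were higher too, with PCSK2, a prohormone convertase, at 6.93. In every comparison the hormone list also held CHGA, CHGB and TTR, which do not encode islet hormones. CHGA and CHGB are members of the secretory list too, and TTR of the alpha-cell list, so these lists are not independent. The endocrine precursor list had a median of 3.75 with 7 of 10 higher, such as PAX4 (6.15), which directs the beta-cell lineage. Serotonin-cell genes (5.08, 5 of 5, LMX1A at 7.25), liver and intestine genes (4.10, 10 of 11, APOC3 at 6.42) and interferon and MHC class I genes (2.41, 8 of 10, IFI6 at 5.54) were higher as well. The median of all 11299 measured genes was 0.018 as reported and -0.22 with TMM factors, a shift to set beside these medians. Without the minimum of 10 CPM the medians of glucose-sensing and beta-cell function genes, 2.35, and BMP targets, -0.20, lay nearer to 0.

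R6d8 WT against EP asked how islet-stage cells in R6 medium differed from the precursors. Hormone and granule genes were higher again, and NEUROG3 was lower. GCG was 24.1-fold higher in R6d8 WT (23.4 to 24.8), INS 10.5-fold, TPH1 6.95-fold and SST 3.58-fold. The most different genes were HDAC9, a histone deacetylase (80.6-fold), and ADCY8, an adenylyl cyclase (87.4-fold). BRINP3 (26.3-fold), EPB41L3 (26.2-fold), NEBL (24.3-fold), GNG3 (21.9-fold), CBLN1 (21.3-fold) and PIP5K1B (21.0-fold) followed, then EEF1A2 (20.2-fold), MME, which encodes the peptidase neprilysin (18.8-fold), and FXYD2, a regulator of the sodium pump (18.4-fold). Lower in R6d8 WT were NEUROG3 (28.7-fold), PPP1R3A (23.1-fold), the transcription factor POU2F2 (10.9-fold), SYNC (7.52-fold), COL14A1 (6.92-fold), RGS5 (6.75-fold), DEFB1 (6.49-fold), BCL2L14 (6.24-fold) and PGA5, a pepsinogen gene (5.56-fold). The long noncoding RNAs MAGI1-AS1, LINC01090 and STARD4-AS1 were 6.48-fold, 6.24-fold and 5.77-fold lower. PGA5 has near-identical relatives, so its level is uncertain.

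By list, 6 of 8 hormone genes were at least 2-fold higher in R6d8 WT (median 1.83) and 14 of 22 secretory genes (median 1.13), such as PTPRN (3.47) and SYT13 (2.99), proteins of the secretory granule and of exocytosis. Glucose-sensing genes had a median of 0.87 with 7 of 15 higher, among them ABCC8 (2.51), which encodes a subunit of the ATP-sensitive potassium channel. Serotonin-cell genes had a median of 1.34 with 5 of 7 higher, such as TRPA1 (3.42), and metallothionein and zinc genes of 2.24 with 4 of 5 higher, such as MT2A (2.40). R6 medium contained zinc, and whether that affected these genes was not tested. Endocrine precursor genes had a median of -0.54 with 2 of 10 lower and 2 higher, SMOC1 (1.24) and BTBD17 (1.35), and 3 of 4 acinar genes were lower (median -1.25). Cell cycle genes were slightly higher (median 0.56, 2 of 20 at least 2-fold: UBE2C at 1.504 and BIRC5 at 1.12). Oxidative phosphorylation genes had a median of -0.15 as reported and 0.00146 with TMM factors, so their direction depended on scaling. TMM factors moved the all-gene median from 0.037 to 0.19. Without the minimum of 10 CPM the medians of endocrine precursor genes, -0.31, and acinar genes, -0.38, lay nearer to 0.

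R7d5 against R6d8 WT compared a later stage in another medium: R7 left out forskolin (which raises cAMP), LDN-193189 (a BMP receptor inhibitor) and Compound E (a gamma-secretase inhibitor) and added the antioxidants N-acetyl cysteine and Trolox. Hormone genes were higher in R7d5 and genes of proliferation and of progenitors lower. SST was 20.05-fold higher (19.6 to 20.5), GAST, the gastrin gene, 12.8-fold, GCG 6.52-fold and INS 3.68-fold. UCN, the gene of the peptide urocortin, was 27.7-fold higher, and the neurofilament genes NEFL and NEFM 18.2-fold and 14.7-fold. C1QTNF4 (14.4-fold), SLC35F4 (9.94-fold), CALY (8.35-fold), the chemokine gene CXCL14 (7.76-fold), the calcium-sensing receptor CASR (6.20-fold) and PCP4 (6.03-fold) were also higher. Lower in R7d5 were RHEX (72.6-fold), HMGA2, a chromatin protein of embryonic cells (37.3-fold), LYPD6B (36.3-fold), PRDM1 (36.2-fold), the desaturase SCD5 (34.3-fold) and ID1 (30.4-fold). FBLN1 (29.5-fold), the nuclear receptor NR5A2 (28.9-fold), CDH6 (26.4-fold), IFITM3 (26.3-fold), the chloride exchanger SLC26A3 (23.8-fold) and FGG (23.1-fold) were lower too. MKI67 was 5.60-fold and SOX9 4.71-fold lower.

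By list, 19 of 20 cell cycle genes were at least 2-fold lower in R7d5 (median -2.42), such as CENPF (-3.41), and 6 of 9 progenitor genes (median -2.04), such as ONECUT1 (-4.07). BMP targets (median -1.84, 4 of 6 lower, ID3 at -3.80), Notch genes (-1.64, 5 of 7, NOTCH2 at -3.03) and ERK targets (-1.15, 5 of 10) were lower in the library without the BMP receptor and gamma-secretase inhibitors. The mix of cells differed too. Clusters 8 and 10, which matched progenitor markers, held 14.5% and 10.2% of R6d8 WT but 0.603% and 0.293% of R7d5. FGG, SLC26A3 and CDH6, named above, were among their leading genes. Proliferating-like cells were 7.16% and 0.293%. Within classes INS was also higher in R7d5: 44742 against 24456 CPM in alpha-like, 63619 against 37520 in beta-like and 16967 against 6843 in enterochromaffin-like cells. In alpha-like cells GCG (16408 against 6585 CPM) and SST (1081 against 95.8) were higher and GHRL (58.7 against 369) was lower. Only hormone and related marker genes were set side by side by class, and cells of a class lay mostly in different clusters. Medium, stage and cell mix therefore cannot be told apart. Interferon and MHC class I genes had a median of -1.66 with 7 of 11 lower, such as IFITM1 (-3.85) and HLA-B (-2.66). In the cAMP list, whose median was -0.55, the 3 members at least 2-fold lower were FOSB (-3.48), NR4A3 (-3.32) and NR4A1 (-2.14), immediate early genes. The immediate early and heat shock list, whose genes also respond to handling, had a median of -0.74 (percentile 0.1) with 6 of 12 lower, such as FOS (-2.01) and EGR1 (-1.56), and 2 higher, HSPA1A (1.97) and HSPA1B (1.09). Antioxidant genes had a median of -0.36 (percentile 13.5) with PRDX1 (-1.11) as the 1 of 9 members past 2-fold. Of 8 measured members of the hormone list, 6 were higher (median 1.75) and GHRL was lower (-1.56). Secretory genes had a median of 0.77 with 5 of 23 higher, such as SCG3 (1.86), and alpha-cell genes of 0.82 with 5 of 12 higher. The all-gene median was -0.20 as reported and -0.018 with TMM factors. Islet transcription factors (-0.046, or 0.13 with TMM factors), serotonin-cell genes (-0.10, or 0.13) and NKX6-1 (-0.14, or 0.041) changed direction with that scaling. Without the minimum of 10 CPM the medians of the Notch pathway, -0.76, BMP targets, -0.94, progenitor genes, -1.26, and antioxidant genes, -0.22, lay nearer to 0.

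**Figure D3:**
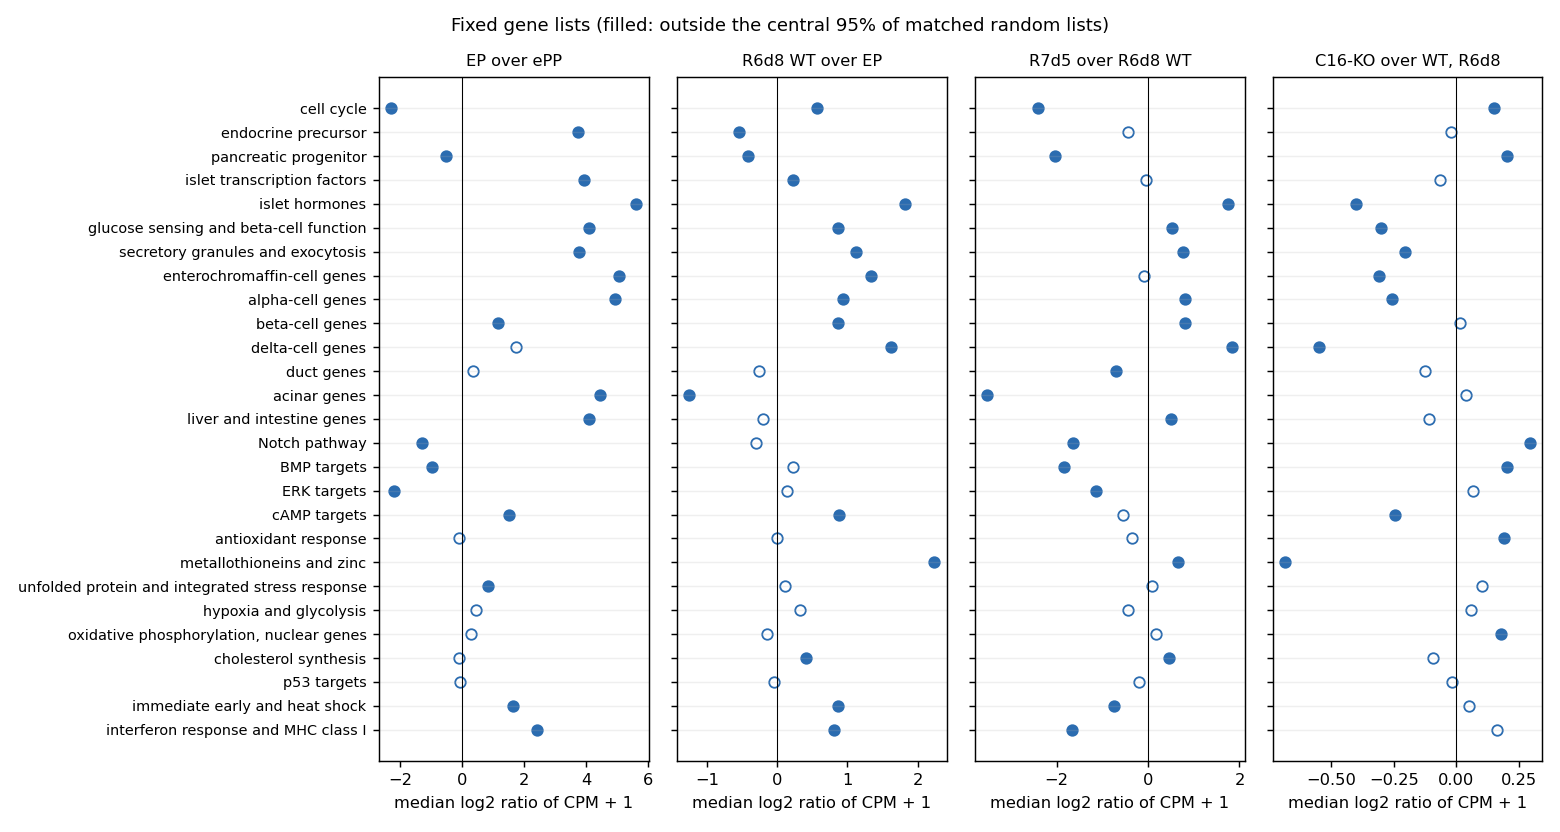
Median log2 ratio of CPM + 1 over the measured members of gene lists fixed in advance, a panel per comparison with its own scale. Filled points lie outside the central 95% of matched random lists; cell cycle genes were at -2.28 in EP over ePP and -2.42 in R7d5 over R6d8 WT.

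R6d8 C16-KO against R6d8 WT set the knockout beside the wild type at the same day in the same medium. The labels do not say which gene C16 stands for, so the targeted gene could not be checked in any library. Glucagon and insulin transcripts were lower in the C16-KO library: GCG 4.01-fold (3.98 to 4.05; 290.5 against 1166 CPM) and INS 2.06-fold (2.05 to 2.06). With UMIs summed over all cells, 1.53% of 11045 measured genes differed at least 2-fold. Without replicate libraries this share does not show whether the difference was narrow or broad. The gene with the highest ratio was LRRC61 (chromosome 7, 150322639 to 150338150, hg38), which had 13135 UMIs in C16-KO and 2 in WT, a ratio of 5777 with a counting interval of 1599 to 47706. LRRC61 overlaps ZBED6CL on the same strand, so its counts are uncertain. CYP17A1, a steroid hydroxylase, was 25.1-fold higher, SYT11, a synaptotagmin, 12.2-fold, the apolipoprotein gene APOA4 10.8-fold, the receptor phosphatase PTPRT 7.97-fold and the bile acid enzyme BAAT 6.71-fold. MIR4713HG (4.59-fold), the incretin gene GIP (4.28-fold), the caspase regulator CFLAR (3.96-fold), RELN (3.82-fold), FKBP11 (3.81-fold) and POU2F2 (3.34-fold) were also higher. Some of these genes led clusters whose share differed between the libraries. RELN and PTPRT were leading genes of unnamed cluster 19, which held 7.11% of C16-KO and 2.08% of WT cells. POU2F2 was a leading gene of precursor-like cluster 6, at 0.967% and 0.144%. Within cluster 19 PTPRT was at 529.5 CPM in C16-KO and 17.5 in WT.

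Lower in C16-KO were S100A6, a calcium-binding protein (9.73-fold; 14.7 against 142.5 CPM), EPB41L3 (4.60-fold), BEX5 (4.50-fold), BRINP1 (3.89-fold), ZFPM2 (3.66-fold), LRFN2 (3.58-fold), ASTN2 (3.56-fold), PPP1R17 (3.43-fold), ZNF83 (3.43-fold), FAM163A (3.12-fold) and the cation channel TRPM3 (2.79-fold). TPH1 was 1.24-fold lower, and NEUROG3 was 2.98-fold higher at low levels (4.78 against 1.60 CPM). The precursor-like class, which is named by NEUROG3, held 77 cells of C16-KO and 11 of WT. PDX1 and SOX9 were 1.21-fold and 1.23-fold higher, and NKX6-1 stood at 77.6 and 76.9 CPM. SST was 1.51-fold higher, but at -0.00465 on the log2 scale when called doublets were kept. By list, hormone genes had a median of -0.40 (percentile 0.0), with INS and GCG as the 2 of 8 past 2-fold. Metallothionein and zinc genes had a median of -0.68 with 0 of 5 past 2-fold, and the lowest member, MT1F, at -0.998. Glucose-sensing genes had a median of -0.30 with 1 of 15 past 2-fold, the calcium channel CACNA1D (-1.09), and serotonin-cell genes of -0.31 with 1 of 7, TRPA1 (-1.82). Within enterochromaffin-like cells the serotonin-cell median was -0.065 (percentile 36.6). It was -0.066 in beta-like, -0.41 in alpha-like and -0.66 in proliferating-like cells. Secretory genes (-0.20) and alpha-cell genes (-0.26) were lower at the median, and cell cycle (0.15), Notch (0.29), BMP target (0.20) and progenitor genes (0.20) were higher, with 0 members of those 4 lists past 2-fold. MKI67 itself was at -0.069. Within proliferating-like and enterochromaffin-like cells the cell cycle medians were -0.016 and -0.45. Beta-cell genes had a median of 0.014 with a counting interval that held 0, and -0.024 with TMM factors. Without the minimum of 10 CPM the medians of serotonin-cell genes, -0.19, and BMP targets, 0.12, lay nearer to 0.

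**Figure D4:**
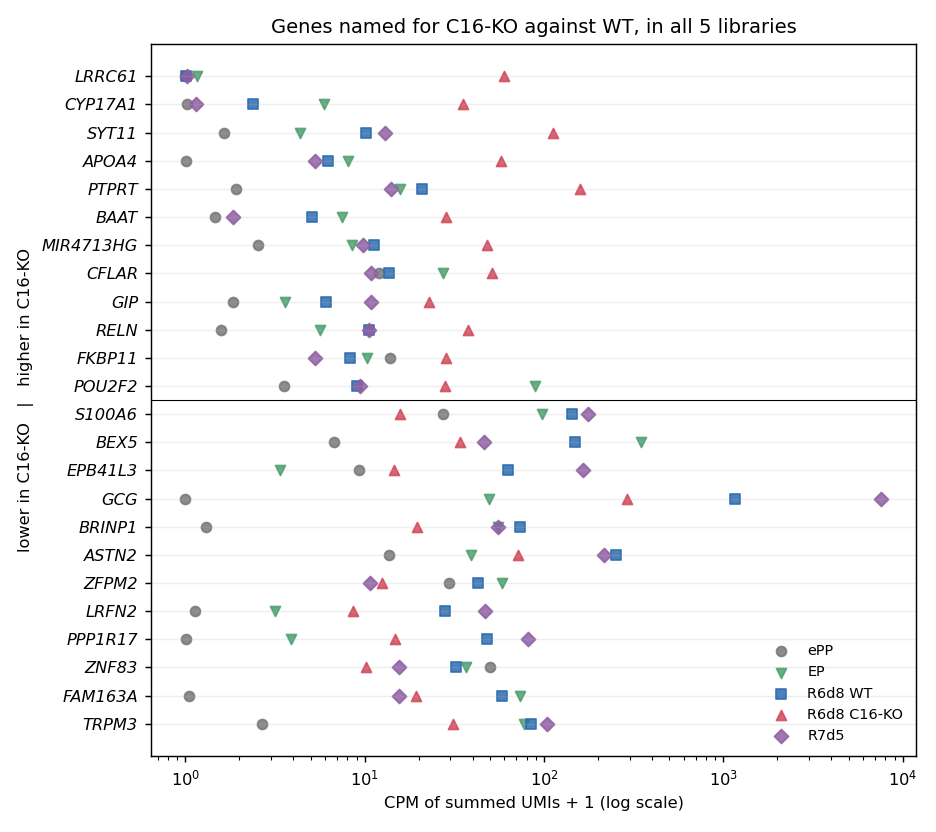
CPM + 1 (log scale) in all 5 libraries of the 12 genes with the highest and the 12 with the lowest ratio in C16-KO over WT. S100A6 was at 14.7 CPM in C16-KO and 142.5 CPM in WT.

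Within classes, the comparison of C16-KO with WT could be made for alpha-like (1204 and 1381 cells), beta-like (470 and 553), enterochromaffin-like (2077 and 2085) and proliferating-like cells (659 and 548). In alpha-like cells INS was 2.61-fold lower in C16-KO (9357 against 24456 CPM) and GCG 3.46-fold lower (1902 against 6585 CPM). In beta-like cells INS was 1.22-fold lower (30665 against 37520 CPM), and in enterochromaffin-like cells TPH1 was 1.12-fold lower (1274 against 1428 CPM), a difference not seen within cluster 7 (1260 against 1287 CPM) or cluster 9 (1512 against 1443 CPM). RNA free in the droplets was not measured, so the level in the lowest cluster of each library was used as a stand-in. For INS this was 467 CPM in C16-KO and 1245 in WT. For GCG it was 10.8 CPM in C16-KO (cluster 9) and 75.9 in WT (cluster 14). GCG in beta-like cells (16.1 and 146 CPM) and in enterochromaffin-like cells (15.8 and 159 CPM) was near that level in C16-KO and above it in WT. Cluster 9 is itself enterochromaffin-like, so for that class the C16-KO level is no separate background. SST was 2.83-fold higher in alpha-like cells of C16-KO (270.9 against 95.8 CPM) and 4.74-fold lower in beta-like cells (25.9 against 123 CPM). On the log2 scale the alpha-like ratio was 1.49, and 0.83 at Leiden resolution 2. The share of alpha-like cells with a SST UMI was 11.1% (9.36 to 13.0) in C16-KO against 12.6% (10.9 to 14.5) in WT in cells thinned to 5000 UMIs and 21.9% against 26.3% unthinned, with 14 and 50 cells left out. In beta-like cells the thinned shares were 4.35% and 9.35%, the unthinned ones 15.5% and 25.7%, and 10 and 18 cells were left out. As a background, proliferating-like cells held a SST UMI in 2.60% and 2.76% of thinned and 15.2% and 13.3% of unthinned cells, with 6 and 5 left out. Median depths, C16-KO first, were 24492 and 21422 UMIs for alpha-like, 32351 and 32467 for beta-like and 36306 and 33140.5 for proliferating-like cells. Within cluster 2 alone (1194 and 1294 alpha-like cells) SST was 2.86-fold higher in C16-KO, and within cluster 15 alone (468 and 514 beta-like cells) it was 4.74-fold lower. Cluster 18 held 2 beta-like cells of C16-KO and 39 of WT, with SST at 589 CPM in the latter.

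LRRC61 had 0 UMIs in WT cells of each compared class and was at least 643-fold higher in alpha-like, 418-fold in beta-like, 1053-fold in enterochromaffin-like and 312-fold in proliferating-like cells, each against a floor of 3 counts over the class. SYT11 was 13.1-fold higher in alpha-like, 10.4-fold in beta-like and 13.3-fold in enterochromaffin-like cells, and PTPRT 37.1-fold higher in proliferating-like, 8.34-fold in alpha-like and 3.65-fold in beta-like cells, with 59.1 against 33.4 CPM in enterochromaffin-like cells. GNGT1, a G protein subunit of the transducin family, was 32.1-fold, 24.7-fold and 9.56-fold higher in alpha-like, beta-like and enterochromaffin-like cells. GIP was 6.07-fold higher in alpha-like and 6.68-fold in beta-like cells, the glutathione transferase MGST1 5.20-fold in beta-like and 5.62-fold in enterochromaffin-like cells, and C2orf74 18.7-fold in alpha-like and 25.7-fold in enterochromaffin-like cells. S100A6 was 10.5-fold, 7.74-fold, 8.80-fold and 10.1-fold lower in alpha-like, beta-like, enterochromaffin-like and proliferating-like cells, and BEX5 5.13-fold, 5.42-fold, 6.51-fold and 4.32-fold lower. UCN (6.01-fold) and OPCML (6.63-fold) were lower in alpha-like cells, and 6.25-fold and 6.58-fold lower within cluster 2 alone. NEFL (4.65-fold), PCP4 (4.92-fold) and ASTN2 (4.96-fold) were lower in beta-like cells, and 1.28-fold, 3.72-fold and 4.76-fold lower within cluster 15 alone. Of the NEFL UMIs of WT, 994 lay in the 39 cells of cluster 18 and 298 in the 514 cells of cluster 15. Also lower were LRFN2 (6.42-fold), FGD5 (6.56-fold) and EPB41L3 (4.49-fold) in enterochromaffin-like cells. NEUROG3 was 13.7-fold higher in enterochromaffin-like cells of C16-KO, at 7.16 against 0.522 CPM. The enterochromaffin-like cells of the libraries lay in different clusters, and differences of these genes were mostly smaller within 1 cluster. In cluster 7 (1980 C16-KO and 161 WT cells) LRFN2 was at 7.66 against 15.4 CPM, FGD5 at 5.71 against 10.8, EPB41L3 at 34.5 against 49.5, GNGT1 at 24.6 against 5.98 and NEUROG3 at 7.54 against 1.14 CPM, the last on 4 WT UMIs. In cluster 9 (80 and 1700 cells) they were at 15.4 against 53.3, 6.11 against 41.9, 79.4 against 173.6, 22.4 against 2.12 and 0.873 against 0.474 CPM, the last on 3 C16-KO UMIs.

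By list, hormone genes had medians of -0.33 in alpha-like, -0.29 in beta-like, -0.32 in enterochromaffin-like and -0.92 in proliferating-like cells. In proliferating-like cells INS (500 against 1283 CPM) was near the level of the lowest cluster of each library. Glucose-sensing genes, lower over all cells, had medians of -0.052 in alpha-like and 0.016 in beta-like cells, and of -0.45 (-0.24 after adjustment for gene length) in enterochromaffin-like and -0.49 in proliferating-like cells. Metallothionein and zinc genes had medians of -0.80, -0.49 and -0.88 in alpha-like, beta-like and enterochromaffin-like cells. Oxidative phosphorylation genes were higher in enterochromaffin-like cells (median 0.52, or 0.28 after adjustment for gene length, with 0 of 20 past 2-fold), and had medians of 0.23 and 0.17 in alpha-like and beta-like cells and -0.07 in proliferating-like cells. BMP targets had medians of 0.38, 0.74 and 0.52 in alpha-like, beta-like and enterochromaffin-like cells, with 3 of 6 members past 2-fold in beta-like cells. After adjustment for gene length those medians were 0.28, 0.62 and 0.19.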

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

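The tests of cell mix, software version, line difference, free RNA and INS in GCG-high cells were chosen after the results were seen; those of chromosome gain, GCG-high cells, less advanced state and gene length were not. SST went opposite ways in the classes of the C16-KO library: its summed level was 2.83-fold higher in alpha-like cells and at 0.211 of the WT level in beta-like cells. The difference between the classes was not tested. At Leiden resolution 2 the alpha-like log2 ratio was 0.83.

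In the C16-KO library 6 genes reached 20 CPM or more and were at least 4-fold higher than in each of the other 4 libraries. The count the other way was 0 genes, but that rule asked for 20 CPM or more in each of the other 4 libraries, ePP and EP included. It was thus the stricter rule, and the counts do not show that differences went mostly one way. A different mix of classes was argued against for each, since with WT cells reweighted to the C16-KO shares their log2 ratios were 5.87 (LRRC61), 3.85 (CYP17A1), 3.56 (SYT11), 2.81 (APOA4), 3.01 (PTPRT) and 2.04 (MIR4713HG); APOA4 lay mostly in cluster 23, with 89.8% of its C16-KO UMIs. A gain of chromosome segments as a cause common to all 6 genes was argued against, since the 122 neighbours within 1 Mb had a median of -0.00862. That median pools neighbours on different chromosomes, so a gain at a single locus could not be seen. A software version was argued against too, since the number of header versions among the R6d8 libraries was 1.0. A difference between the lines other than the knockout cannot be told apart from it, with 1.0 C16-KO library. An effect of the knockout on these genes stayed open and untested.

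INS and GCG were lower in alpha-like cells of C16-KO. Free RNA was argued against as the whole cause for GCG: the lowest clusters, the stand-in for free RNA, differed by 1.39% of the GCG difference of alpha-like cells. Fewer GCG-high cells may account for part of the GCG difference, since cells at or above 1000 CPM were 8.56% of 1204 in C16-KO and 26.0% of 1381 in WT, while their median GCG level differed by -0.0945 on the log2 scale. They were argued against as the whole cause for INS, whose median in those same cells differed by -1.06 (-1.70 to -0.603 over cells). In the other alpha-like cells, which were most of the class, median INS was lower in C16-KO too, at 1146 against 9508 CPM in WT. A less advanced state may also be part of it: genes at least 4-fold higher in R7d5 than in EP had a median of -0.262 and genes at least 4-fold lower one of 0.176, though within enterochromaffin-like cells the lower set had -0.119, or 0.039 adjusted for gene length. The drop of the higher set was not particular to alpha-like cells. Its medians were -0.314 in beta-like, -0.317 in enterochromaffin-like and -0.343 in proliferating-like cells. The sets came from all cells of libraries that differed in cell mix, and the higher set includes INS and GCG themselves.

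Hormone, secretory and glucose-sensing lists were lower in C16-KO over all cells. Gene length was argued against, since after adjustment no list moved halfway to 0; the glucose-sensing list, which kept the smallest part of its median, was at -0.301. With cells reweighted to the same mix the secretory median was -0.0583, so a different mix of cells may account for it, while the glucose-sensing median stayed at -0.283; within classes it was -0.45 (-0.24 adjusted for gene length) in enterochromaffin-like and -0.49 in proliferating-like cells, but -0.052 in alpha-like and 0.016 in beta-like cells. The reweighted hormone median, -0.216, lay between the limits set for and against a different mix, so that test did not decide. What remained is not due to the mix of the reweighted classes, though a different mix within a class was not removed. Within alpha-like and beta-like cells the hormone medians were -0.33 and -0.29.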

How the results depend on the processing

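The alternative that put doublets at their automatic thresholds was chosen after seeing the data; the others were chosen before the data were examined. As reported, the hormone list had medians of 5.63 (EP over ePP), 1.83 (R6d8 WT over EP), 1.75 (R7d5 over R6d8 WT) and -0.40 (C16-KO over WT). INS and GCG in alpha-like cells were at -1.39 and -1.79, INS in beta-like cells at -0.29, and the beta-like and enterochromaffin-like shares differed by -1.32 and -1.13 percentage points.

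With TMM factors the hormone medians were 1.97 for R6d8 WT over EP and 1.93 for R7d5 over R6d8 WT, alpha-like INS and GCG -1.44 and -1.85, and beta-like INS -0.33. Of results whose intervals lay off 0, signs reversed for oxidative phosphorylation in R6d8 WT over EP (0.00146) and, in R7d5 over R6d8 WT, for islet transcription factors (0.13), enterochromaffin-cell genes (0.13) and NKX6-1 (0.041). With median-of-ratios factors the hormone medians were 1.99, 1.95 and -0.45, and the same 4 reversed (0.021, 0.15, 0.15 and 0.059), as did acinar genes in C16-KO over WT (-0.00980). With the total without hormone genes the R7d5 hormone median was 1.82 and islet transcription factors reversed (0.021). With pseudocount 0.1 the medians were 8.92 for EP over ePP and 1.89 for R6d8 WT over EP; with pseudocount 10 they were 3.48, 1.18, 1.55 and -0.32 in the order above.

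With the mean of per-cell CPM the hormone medians were 1.66 for R7d5 and -0.30 for C16-KO, alpha-like GCG -1.72 and beta-like INS -0.27; enterochromaffin-cell genes in R7d5 (0.15) and acinar genes in C16-KO (-0.13) reversed. With no cell filter they were 1.71 and -0.32, the enterochromaffin-like difference -4.77 points, and MKI67 in C16-KO over WT reversed (0.042). With doublets kept the medians were 2.14, 1.76 and -0.46 for R6d8 WT, R7d5 and C16-KO, and acinar genes (-0.000824) and SST (-0.00465) reversed in C16-KO. With automatic doublet thresholds the R7d5 median was 1.76 and the beta-like difference -2.49 points. With no CPM minimum the medians were 5.35, 1.74, 1.62 and -0.28, and antioxidant genes in EP over ePP (0.055) and liver and intestine genes (0.053) and BMP targets (-0.046) in R6d8 WT over EP reversed. Beta-like INS was -0.27 at Leiden resolution 2 and -0.26 when clustering left out the 2-fold genes, which put alpha-like INS at -1.37. The beta-like difference was -0.150 points with the mitochondrial limit at 10% and -0.206 with the R6d8 libraries clustered alone. Some results whose counting intervals held 0 also had the other sign. In C16-KO over WT, beta-cell genes and NKX6-1 (both 0.014 as reported) were at -0.024, -0.036 and -0.024 with TMM factors, median-of-ratios factors and no cell filter. Delta-cell genes in EP over ePP (1.74 on 4 genes) were at -0.23 with TMM factors and -0.24 with median-of-ratios factors, and p53 targets in R6d8 WT over EP (-0.042) at 0.105 and 0.12, and at 0.13 with no CPM minimum. The cause was not tested for any of these.

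Of all values under the alternatives, 358 of 558 moved by less than their counting interval in C16-KO over WT, 290 of 548 in EP over ePP, 291 of 549 in R6d8 WT over EP and 233 of 549 in R7d5 over R6d8 WT; of the class shares, 100 of 174. The enterochromaffin-like difference turned positive at Leiden resolution 2 (0.068) and with automatic doublet thresholds (0.0036). The proliferating-like share of ePP ran from 17.6% to 58.7% and the precursor-like share of EP from 11.6% to 38.0%. No paired analysis was possible because each group had 1 library.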

Other observations

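The levels of 2 other hormone genes differed by class. GAST, the gastrin gene, was at 11988 CPM in alpha-like and 5822 CPM in beta-like cells of R7d5, and at 2125 and 1165 CPM in R6d8 WT and 1467 and 382 CPM in R6d8 C16-KO. The lowest cluster held 353 CPM of GAST in R7d5. GHRL, the ghrelin gene, was at 1465 CPM in the 90 alpha-like cells of EP, 369 in those of R6d8 WT, 538 in those of C16-KO and 58.7 in those of R7d5. Few of the alpha-like cells of EP held glucagon transcripts: 23.0% (14.6 to 33.2) had a GCG UMI after thinning and 24.4% unthinned.

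Markers of other cell types were measured too. No mesenchyme marker of 10 reached 10 CPM in any of the 5 libraries. LYZ, a lysozyme gene of immune and gut cells, was at 160 CPM in EP, 419 in R6d8 WT, 344 in R6d8 C16-KO and 62.7 in R7d5. L1TD1, a gene of pluripotent cells, was at 126, 153, 50.0, 85.5 and 5.64 CPM from ePP to R7d5, and EGFL7 at 182 CPM in R7d5.

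Over all cells of C16-KO against WT, longer genes had lower ratios: with the genes in 5 equal groups by span, medians ran from 0.124 in the shortest to -0.104 in the longest. Within classes they ran from 0.264 to -0.346 in enterochromaffin-like, from 0.126 to -0.0323 in alpha-like and from 0.115 to -0.0747 in beta-like cells, and the other way, from -0.0179 to 0.0758, in proliferating-like cells. The nuclear RNAs MALAT1 and NEAT1 were at 9560 and 634 CPM in C16-KO and 8632 and 454 CPM in WT.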
